A study of Homo sapiens with 12 samples.

How the data were processed

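RNA-seq libraries of 12 HCT116 samples were analysed, 3 in each of 4 groups: control and cystine-deprived cells (0 mM cystine) at 24 h and 48 h. Each sample's group and replicate number came from its title in the labels. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase and made into libraries by standard Illumina protocols, and the medium held 10% fetal bovine serum. Strandedness of the libraries is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

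The deposited table holds estimated counts per gene, 1 column per sample, which the authors left without normalization. They are not all whole numbers, and their column totals differ between samples. The submitters' processing notes name fastp, HISAT and RSEM and the build GRCh38, without versions, roles or order, and the annotation release is not given in the sources used here. The labels mention a TPM table, but these columns have totals that differ between samples, so the values were treated as estimated counts and not as TPM. Such estimates split reads between near-identical copies of a gene, which makes single members of families such as KRT16, the metallothioneins, HSPA1A and HSPA1B, the histones and the ribosomal proteins uncertain. The other column used is the gene length in the deposited table.

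Of 60987 rows, 316 had no gene name and were left out of library sizes and tests; they held 1.55% of counts in control cells at 24 h, 1.2% in control cells at 48 h, 1.06% in deprived cells at 24 h and 0.762% in deprived cells at 48 h. Mitochondrial transcripts held 6.99%, 8.54%, 6.55% and 7.83% in the same order. Estimated counts were rounded to whole numbers. Genes passing edgeR's filterByExpr (minimum count 10, minimum total count 15) were kept, which gave 16994 genes, and TMM factors were computed.

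All 12 samples entered 1 fit of 4 group means with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), without a replicate block, and 5 contrasts were tested with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the root of the F statistic. The biological coefficient of variation was 6.4%. CPM use TMM-scaled library sizes and are given as mean ± SD with n = 3. Replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom of 3.08 to 8.81, so no library was treated as deposited a second time. This does not tell separate cultures from technical repeats.

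Of 36 gene lists fixed before the data were examined, 32 had at least 5 tested members and were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the lists within a contrast. The correlation estimated per list and fry were alternatives. The lists share members, such as SLC7A11 and HMOX1, and so are not independent. A member is said to rise or fall if its adjusted p over all genes is under 0.05.

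Named genes followed a rule also fixed before the data were examined. It took the 8 largest rises and 8 largest falls at each time, and the 5 largest in each direction for the other contrasts. These had to pass the threshold, have a mean of at least 5 CPM, a plain gene symbol and, except for the interaction, groups that do not overlap. It also took the 4 members with the smallest adjusted p of each list described, and a fixed set around cystine uptake, glutathione, ferroptosis and hypoxia. Some genes that the rule takes are not reported here. Coordinates are those of GENCODE release 29 on GRCh38, matched by gene identifier; this release is not stated to be the authors' own.

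The steps were tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes per time. In the comparison at 24 h, 48.4% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 89.4% of those changed 4-fold were recovered among 16653 tested, and 4.7% of calls were false. At 48 h these were 62.1%, 65.2%, 98.5% and 6.9%. A simulated list of 30 genes raised 1.5-fold was called, and 0 of 31 random lists were. Genes were drawn independently, so the simulation could not show false list calls that arise from correlated members. It also changed far fewer genes than were called in the data, so its rates may not hold there.

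Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter, a stricter filter (mean of at least 5 CPM), the replicate number as a block, only the compared groups in the fit, and leaving out each of the 12 samples. Scaling by library totals was added after seeing the data. Protein sequences for a test in the closing section came from the GENCODE release 29 transcripts, translated with Biopython 1.88, and rank correlations from scipy 1.17.1.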

Results

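RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, kept in full DMEM or in DMEM with 0 mM cystine. Cystine is the oxidised dimer of cysteine. The series concerns cysteine metabolism in colorectal cancer, and the comparisons ask which transcripts respond when cystine is withheld. Cells were harvested after 24 h or 48 h, which gave 4 groups of 3 samples, control and deprived at each time. The total estimated count per sample lay between 19146108 and 24179533, and 16994 genes had enough counts to be tested. The labels describe a wash and fresh medium for the deprived cells only, so each comparison of media may include that step. They do not say that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The first principal component held 60.5% of the variance. It placed control samples at -54.9 to -47, deprived samples at 24 h at 25.5 to 28.2 and deprived samples at 48 h at 72.4 to 76.9.

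The first comparison asked what 24 h without cystine changed. Transcripts of the cystine importer rose. SLC7A11, its transport subunit (chromosome 4, 138164097 to 138242349, GRCh38), went from 61.5 ± 10 to 551 ± 21.1 CPM (SD, n = 3), and SLC3A2, its partner chain, from 165 ± 9.97 to 766 ± 30.9 CPM. CHAC1, a glutathione-degrading enzyme (chromosome 15, 40952962 to 40956519), rose 8.52-fold. HMOX1, a haem oxygenase (chromosome 22, 35380361 to 35394214), rose 16.4-fold, from 16.6 ± 0.414 to 271 ± 6.28 CPM. UPP1, a uridine phosphorylase (chromosome 7, 48088628 to 48108733), rose 30.2-fold, from 10.3 ± 0.869 to 311 ± 15.7 CPM. GPX4, the glutathione peroxidase that reduces lipid peroxides (chromosome 19, 1103926 to 1106791), fell by 0.49 ± 0.06 on the log2 scale (SE), from 180 ± 8.06 to 128 ± 3.75 CPM.

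The 8 largest rises at 24 h, as log2 fold change ± SE, were SPX 5.52 ± 0.34, UPP1 4.91 ± 0.08, HKDC1 4.28 ± 0.22, LCN2 4.13 ± 0.18, NRP1 4.11 ± 0.10, IL20RB 4.04 ± 0.17, HMOX1 4.03 ± 0.09 and ANGPT4 3.68 ± 0.15. The largest falls were FAM220A -4.31 ± 0.75, CD164L2 -2.65 ± 0.16, SLC2A12 -2.37 ± 0.15, ANK1 -2.26 ± 0.17, AXIN2 -2.23 ± 0.12, PALM3 -2.19 ± 0.17 and CYP24A1 -2.16 ± 0.08, together with METTL7A, which went from 12.4 ± 0.292 to 1.54 ± 0.0697 CPM. FAM220A varied widely among the control samples, at 11.5 ± 8.62 CPM. SPX was near the floor in control cells, at 0.229 ± 0.201 CPM, so the size of its fold change rests on few counts. By edgeR's quasi-likelihood test, 9451 of 16994 genes changed at an adjusted p under 0.05, with 4886 higher and 4565 lower. Upper-quartile scaling gave 4160 higher and 5300 lower, and scaling by library totals alone, a choice made after seeing the data, gave 4086 and 5320, so the balance of directions depends on the scaling. By at least 2-fold, 823 were higher and 1063 lower.

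Counts of list members are adjusted over all genes, and those adjusted over the list alone were the same wherever no other count is given. Targets of ATF4, a transcription factor of the integrated stress response, rose in 26 of 30 members and fell in 1, with a median log2 fold change of 1.96 (TRIB3 3.30 ± 0.07, DDIT3 3.09 ± 0.08, STC2 2.98 ± 0.07, CEBPG 2.04 ± 0.06). The ATF4 list had an adjusted p of 2.24e-18 by camera, and adjusted p = 0.0737 with an estimated correlation. ASNS rose 4.26-fold, and ATF4 itself rose 1.34-fold. Cytosolic aminoacyl-tRNA synthetases rose in 16 of 20 members and fell in 1, with a median log2 fold change of 0.84 (WARS1 2.64 ± 0.06, AARS1 1.86 ± 0.06). Cytosolic aminoacyl-tRNA synthetases had an adjusted p of 3.03e-09 by camera, and adjusted p = 0.14 with an estimated correlation. Amino acid transporters rose in 11 of 20 members and fell in 6, with a median log2 fold change of 0.29 (SLC7A5 2.10 ± 0.06, SLC7A1 1.81 ± 0.06). Amino acid transporters had an adjusted p of 0.00933 by camera, and adjusted p = 0.14 with an estimated correlation. Endoplasmic reticulum chaperones and unfolded protein response genes rose in 15 of 20 members and fell in 1, with a median log2 fold change of 0.61 (HSPA5 2.22 ± 0.05, HYOU1 1.64 ± 0.05). Chaperones of the endoplasmic reticulum had an adjusted p of 7.85e-08 by camera, and adjusted p = 0.112 with an estimated correlation.

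Targets of NRF2, a regulator of antioxidant genes, rose in 19 of 30 members and fell in 6, with a median log2 fold change of 0.81 (SRXN1 2.30 ± 0.06, FTH1 2.09 ± 0.06, TXNRD1 1.81 ± 0.05). The NRF2 list had an adjusted p of 9.36e-06 by camera, and adjusted p = 0.14 with an estimated correlation. NQO1 rose 2.16-fold. Genes of cysteine and glutathione metabolism went both ways, with 13 up and 13 down of 32 and an adjusted p of 0.698. Their median was -0.01 and their mean 0.15. GCLM and GCLC, subunits of the enzyme that starts glutathione synthesis, rose 3.98-fold and 2.35-fold. CTH, which makes cysteine from cystathionine, was not called (adjusted p = 0.4). CBS, the enzyme before it, and TXNIP were too low to test, with highest estimated counts of 2.41 and 3 in any sample. CBSL, a near-identical copy of CBS, reached at most 3.35. The copies can share reads, so these counts do not tell how strongly CBS was expressed. The lists of ferroptosis regulators (11 up and 13 down of 29, adjusted p = 0.844), selenoproteins (6 up and 10 down of 19, adjusted p = 0.327) and iron-sulfur cluster assembly (10 up and 6 down of 24, adjusted p = 0.492) did not pass camera. TFRC, the transferrin receptor, rose 1.23-fold.

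Sterol synthesis genes rose in 1 of 25 members and fell in 24, with a median log2 fold change of -1.01 (INSIG1 -1.98 ± 0.08, LSS -1.70 ± 0.06). Sterol synthesis genes had an adjusted p of 4.54e-15 by camera, and adjusted p = 0.102 with an estimated correlation. Fatty acid synthesis genes rose in 4 of 16 members and fell in 9, with a median log2 fold change of -0.20 (SCD -0.84 ± 0.05, FASN -1.06 ± 0.08). Fatty acid synthesis genes had an adjusted p of 0.0189 by camera, and adjusted p = 0.21 with an estimated correlation. Glycolysis genes rose in 1 of 15 members and fell in 13 (2 and 13 adjusted over the list alone), with a median log2 fold change of -0.51 (PGK1 -0.82 ± 0.07, PKM -0.76 ± 0.06). Glycolysis genes had an adjusted p of 1.1e-05 by camera, and adjusted p = 0.357 with an estimated correlation. Hypoxia and HIF targets rose in 1 of 25 members and fell in 15, with a median log2 fold change of -0.47 (KDM3A -0.87 ± 0.07, LDHA -0.95 ± 0.08). The hypoxia list had an adjusted p of 0.000342 by camera, and adjusted p = 0.464 with an estimated correlation. The member that rose was VEGFA, by 1.79 ± 0.07, and HIF1A, outside the list, rose 1.38-fold. CA9 was not called (adjusted p = 0.116), but was without control 24 h replicate 1 (adjusted p = 0.032).

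Wnt and beta-catenin targets rose in 0 of 10 members and fell in 9 (0 and 10 adjusted over the list alone), with a median log2 fold change of -0.93 (AXIN2 -2.23 ± 0.12, NKD1 -1.24 ± 0.09). Wnt and beta-catenin targets had an adjusted p of 3.08e-05 by camera, and adjusted p = 0.0737 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes rose in 2 of 42 members and fell in 32 (2 and 34 adjusted over the list alone), with a median log2 fold change of -0.28 (COX6C -0.74 ± 0.06, COX5B -0.72 ± 0.07). Nuclear-encoded oxidative phosphorylation genes had an adjusted p of 2.55e-07 by camera, and adjusted p = 0.359 with an estimated correlation. Mitochondrially encoded transcripts rose in 1 of 13 members and fell in 9 (1 and 10 adjusted over the list alone), with a median log2 fold change of -0.20 (MT-ND3 -0.53 ± 0.06, MT-ND2 -0.43 ± 0.06). Mitochondrially encoded transcripts had an adjusted p of 0.0166 by camera, and adjusted p = 0.586 with an estimated correlation. Interferon-stimulated genes rose in 3 of 25 members and fell in 15, with a median log2 fold change of -0.43 (IFIT1 -1.88 ± 0.18, IFI6 -1.44 ± 0.17). Interferon-stimulated genes had an adjusted p of 0.00615 by camera, and adjusted p = 0.143 with an estimated correlation. Heat shock proteins rose in 2 of 12 members and fell in 8 (3 and 8 adjusted over the list alone), with a median log2 fold change of -0.40 (HSPB1 -1.19 ± 0.07, HSPE1 -1.12 ± 0.06). Heat shock proteins had an adjusted p of 0.00651 by camera, and adjusted p = 0.402 with an estimated correlation.

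Ribosome biogenesis genes rose in 30 of 35 members and fell in 0 (30 and 2 adjusted over the list alone), with a median log2 fold change of 0.48 (DDX21 1.23 ± 0.05, RRP12 1.10 ± 0.06). Ribosome biogenesis genes had an adjusted p of 5.07e-10 by camera, and adjusted p = 0.14 with an estimated correlation. Mitosis and G2/M genes rose in 26 of 40 members and fell in 3 (27 and 3 adjusted over the list alone), with a median log2 fold change of 0.32 (UBE2C 1.04 ± 0.07, CDC20 0.86 ± 0.06). The mitosis list had an adjusted p of 1.97e-05 by camera, and adjusted p = 0.168 with an estimated correlation. Immediate early genes rose in 17 of 22 members and fell in 3, with a median log2 fold change of 0.72 (FOSL1 2.66 ± 0.08, JUN 2.63 ± 0.07). Immediate early genes had an adjusted p of 9.36e-06 by camera, and adjusted p = 0.244 with an estimated correlation. Targets of p53 rose in 16 of 25 members and fell in 5, with a median log2 fold change of 0.32 (GDF15 2.23 ± 0.07, TNFRSF10B 1.23 ± 0.04). Targets of p53 had an adjusted p of 0.00615 by camera, and adjusted p = 0.168 with an estimated correlation. CDKN1A, a cyclin-dependent kinase inhibitor, rose 2.5-fold. Metallothioneins and zinc response genes rose in 4 of 5 members and fell in 0, with a median log2 fold change of 0.83 (MT2A 1.31 ± 0.06, MT1X 1.21 ± 0.08). Their median was 0.13 over the 8 members taken without a filter on low counts. Metallothioneins and zinc response genes had an adjusted p of 0.00615 by camera, and adjusted p = 0.168 with an estimated correlation. Mesenchymal genes rose in 9 of 14 members and fell in 3, with a median log2 fold change of 0.83 (PLAU 1.94 ± 0.07). Mesenchymal genes had an adjusted p of 0.0222 by camera, and adjusted p = 0.391 with an estimated correlation.

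Other lists at 24 h did not pass camera. They were replication-dependent histones (7 up and 0 down of 14, adjusted p = 0.0518), DNA replication and E2F targets (11 up and 16 down of 40, 11 and 17 adjusted over the list alone, adjusted p = 0.222), cytosolic ribosomal proteins (11 up and 12 down of 75, 9 and 10 adjusted over the list alone, adjusted p = 0.698), epithelial junction and keratin genes (10 up and 8 down of 19, adjusted p = 0.252), nucleotide synthesis (10 up and 6 down of 23, adjusted p = 0.326) and NF-kappaB and inflammatory cytokine genes (6 up and 4 down of 15, adjusted p = 0.692). Neither autophagy and lysosome genes (12 up and 12 down of 34, 12 and 13 adjusted over the list alone, adjusted p = 1) nor neural and other cell line markers (1 up and 2 down of 5, adjusted p = 0.623) passed. The sign of the median at 24 h depended on the scaling, the filter or a left-out library for the cysteine, iron-sulfur, NF-kappaB, ribosomal protein and neural lists. Colon differentiation genes and markers of fibroblasts, leukocytes and endothelial cells had 2 to 4 tested members each, too few for the list test. Among them at 24 h, CD68 rose by 1.36 ± 0.12 on the log2 scale, and COL1A1 and EGFL7 fell by 0.83 ± 0.09 and 0.57 ± 0.08. In all, 20 of 32 lists passed camera at 24 h with the preset correlation. With an estimated correlation 0 did, and 9 lists had an unadjusted p under 0.05.

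**Figure D1:**
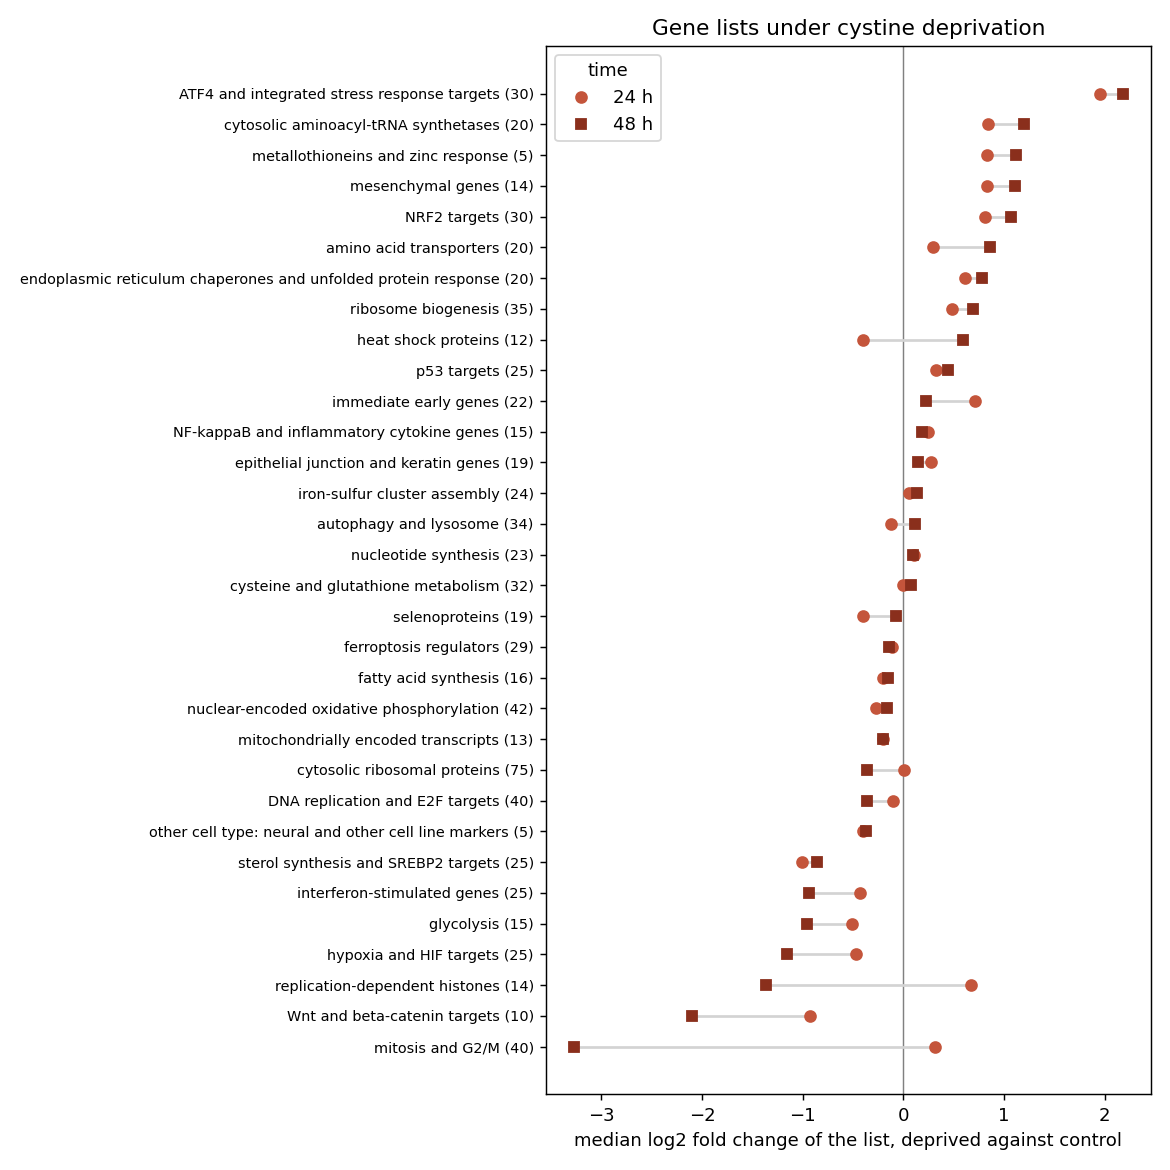
Median log2 fold change of each tested gene list in deprived against control cells (x axis), at 24 h (circles) and 48 h (squares), with the number of measured genes in brackets and a grey line joining both times. The mitosis and G2/M list lies at 0.32 at 24 h and at -3.27 at 48 h. With the processing or a left-out library, the sign changed for the cysteine, iron-sulfur, NF-kappaB, ribosomal protein and neural medians at 24 h and for the NF-kappaB, epithelial junction and neural medians at 48 h.

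The second comparison asked what 48 h without cystine changed. Mitotic transcripts fell in all 40 measured list members. KIF20A, a mitotic kinesin, went from 173 ± 11.3 to 4.4 ± 0.395 CPM (SD, n = 3) and CENPF, a kinetochore protein, from 478 ± 74.1 to 19.2 ± 1.6 CPM. HMOX1 rose 53.4-fold to 992 ± 129 CPM, SLC7A11 20.4-fold to 763 ± 119 CPM, CHAC1 28.4-fold to 156 ± 10.3 CPM and UPP1 43.5-fold to 391 ± 10 CPM. NUPR1, a stress-induced nuclear protein gene (chromosome 16, 28532708 to 28539174), reached 16.4 ± 1.23 CPM. With 2 counts over the 3 control samples and 1088 over the 3 deprived samples, its ratio was 551, with a 95% interval of 152 to 4560 that covers counting error only. GPX4 fell by 1.15 ± 0.06 on the log2 scale (SE), from 185 ± 15.4 to 83.5 ± 5.1 CPM.

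Other large rises at 48 h, as log2 fold change ± SE, were SPX 7.21 ± 0.35, KLHDC7B 6.15 ± 0.26, LCN2 6.02 ± 0.16 and KRT16 4.83 ± 0.29, the last a keratin whose reads can be shared with near-identical copies. SPX was again near the floor in control cells, at 0.116 ± 0.129 CPM. Besides KIF20A and CENPF, the largest falls were those of METTL7A (-6.06 ± 0.22, chromosome 12, 50923472 to 50932517) and of PIF1, a DNA helicase (-5.91 ± 0.18, chromosome 15, 64815632 to 64825668). They also included SPDYA -4.99 ± 0.16, TMSB15A -4.94 ± 0.24, CDC25C -4.78 ± 0.14 and YPEL1 -4.62 ± 0.18. By edgeR's quasi-likelihood test, 11615 of 16994 genes changed at an adjusted p under 0.05, with 5685 higher and 5930 lower. The majority turned, to 4640 higher and 4568 lower, among genes with a mean of at least 5 CPM, and to 5632 and 5542 with only the compared groups in the fit. It grew, to 5203 higher and 6379 lower, under upper-quartile scaling, and to 5463 and 6104 with library totals alone as the scale. By at least 2-fold, 1459 were higher and 2594 lower.

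Mitosis and G2/M genes rose in 0 of 40 members and fell in 40, with a median log2 fold change of -3.27 (KIF20A -5.29 ± 0.08, DLGAP5 -4.47 ± 0.08, MKI67 -3.91 ± 0.07, BUB1 -3.63 ± 0.07). The mitosis list had an adjusted p of 7.12e-26 by camera, and adjusted p = 0.0265 with an estimated correlation. DNA replication and E2F targets rose in 8 of 40 members and fell in 23, with a median log2 fold change of -0.37 (TK1 -2.57 ± 0.06, TYMS -1.70 ± 0.07). DNA replication and E2F targets had an adjusted p of 0.00647 by camera, and adjusted p = 0.543 with an estimated correlation. Cytosolic ribosomal protein genes rose in 1 of 75 members and fell in 62 (2 and 62 adjusted over the list alone), with a median log2 fold change of -0.36 (RPS9 -1.19 ± 0.06, RPL23A -0.86 ± 0.05). Cytosolic ribosomal protein genes had an adjusted p of 1.04e-09 by camera, and adjusted p = 0.528 with an estimated correlation. Many of the ribosomal protein genes have near-identical pseudogene copies that can share reads. Ribosome biogenesis genes rose in 30 of 35 members and fell in 1, with a median log2 fold change of 0.70 (RRP12 1.69 ± 0.06, DDX21 1.56 ± 0.05). Ribosome biogenesis genes had an adjusted p of 4.82e-09 by camera, and adjusted p = 0.139 with an estimated correlation.

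Targets of ATF4 rose in 28 of 30 members and fell in 1, with a median log2 fold change of 2.18 (STC2 3.72 ± 0.07, SESN2 3.58 ± 0.08, PPP1R15A 3.49 ± 0.08, TRIB3 3.48 ± 0.07). The ATF4 list at 48 h had an adjusted p of 7.25e-15 by camera, and adjusted p = 0.0898 with an estimated correlation. Cytosolic aminoacyl-tRNA synthetases rose in 18 of 20 members and fell in 2, with a median log2 fold change of 1.20 (WARS1 3.63 ± 0.07, GARS1 2.15 ± 0.06). Cytosolic aminoacyl-tRNA synthetases had an adjusted p of 2.5e-08 by camera, and adjusted p = 0.139 with an estimated correlation. Amino acid transporters rose in 13 of 20 members and fell in 4, with a median log2 fold change of 0.86 (SLC7A5 2.86 ± 0.06, SLC7A1 2.12 ± 0.06). Amino acid transporters had an adjusted p of 0.00182 by camera, and adjusted p = 0.114 with an estimated correlation. Endoplasmic reticulum chaperones and unfolded protein response genes rose in 16 of 20 members and fell in 3, with a median log2 fold change of 0.78 (HSPA5 2.04 ± 0.05, HYOU1 1.87 ± 0.05). Chaperones of the endoplasmic reticulum had an adjusted p of 6.89e-06 by camera, and adjusted p = 0.139 with an estimated correlation. Targets of NRF2 rose in 21 of 30 members and fell in 4, with a median log2 fold change of 1.07 (FTH1 3.04 ± 0.06, SRXN1 2.57 ± 0.06, TXNRD1 2.43 ± 0.05). The NRF2 list at 48 h had an adjusted p of 9.62e-07 by camera, and adjusted p = 0.114 with an estimated correlation. CTH rose 1.71-fold, GCLM 6.84-fold, GCLC 2.07-fold and TFRC 2.19-fold.

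Heat shock proteins rose in 8 of 12 members and fell in 2, with a median log2 fold change of 0.59 (DNAJB1 1.70 ± 0.08, HSPA8 1.45 ± 0.07, HSPA1B 1.36 ± 0.10). Heat shock proteins had an adjusted p of 0.0153 by camera, and adjusted p = 0.528 with an estimated correlation. HSPA1B shares sequence with HSPA1A. Targets of p53 rose in 18 of 25 members and fell in 7, with a median log2 fold change of 0.44 (GDF15 2.37 ± 0.07, CCNG1 -1.73 ± 0.06). Targets of p53 had an adjusted p of 0.00893 by camera, and adjusted p = 0.188 with an estimated correlation. CDKN1A rose 4.01-fold. Metallothioneins and zinc response genes rose in 4 of 5 members and fell in 1, with a median log2 fold change of 1.12 (MT1X 1.62 ± 0.07, MT2A 1.24 ± 0.06). Metallothioneins and zinc response genes had an adjusted p of 0.0168 by camera, and adjusted p = 0.241 with an estimated correlation. Hypoxia and HIF targets rose in 1 of 25 members and fell in 23, with a median log2 fold change of -1.16 (ALDOC -3.22 ± 0.13, ADM -1.79 ± 0.08, KDM3A -1.62 ± 0.07). The hypoxia list had an adjusted p of 7.41e-08 by camera, and adjusted p = 0.298 with an estimated correlation. VEGFA was again the member that rose, by 1.71 ± 0.07, and HIF1A rose 1.77-fold. CA9 fell by 2.66 ± 0.29 on the log2 scale, from 6.33 ± 1.57 to 0.993 ± 0.224 CPM.

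Glycolysis genes rose in 1 of 15 members and fell in 13, with a median log2 fold change of -0.95 (ALDOA -1.65 ± 0.09, LDHA -1.51 ± 0.08). Glycolysis genes had an adjusted p of 1.03e-05 by camera, and adjusted p = 0.382 with an estimated correlation. Sterol synthesis genes rose in 2 of 25 members and fell in 23, with a median log2 fold change of -0.86 (SQLE -1.40 ± 0.06). Sterol synthesis genes had an adjusted p of 6.15e-08 by camera, and adjusted p = 0.146 with an estimated correlation. Wnt and beta-catenin targets rose in 0 of 10 members and fell in 10, with a median log2 fold change of -2.10 (NOTUM -3.08 ± 0.19, DKK1 -2.36 ± 0.08). Without a filter on low counts the median was -1.23 over 13 members. Wnt and beta-catenin targets had an adjusted p of 0.000229 by camera, and adjusted p = 0.0898 with an estimated correlation. Interferon-stimulated genes rose in 4 of 25 members and fell in 17 (4 and 18 adjusted over the list alone), with a median log2 fold change of -0.94 (IFI6 -3.36 ± 0.19, IFITM3 -1.32 ± 0.06). Interferon-stimulated genes had an adjusted p of 0.00154 by camera, and adjusted p = 0.114 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes rose in 6 of 42 members and fell in 22, with a median log2 fold change of -0.16 (COX6C -1.03 ± 0.06, NDUFS1 0.72 ± 0.05). Nuclear-encoded oxidative phosphorylation genes had an adjusted p of 0.0187 by camera, and adjusted p = 0.709 with an estimated correlation. Mitochondrially encoded transcripts rose in 1 of 13 members and fell in 10 (1 and 11 adjusted over the list alone), with a median log2 fold change of -0.21 (MT-CYB -0.78 ± 0.06, MT-CO3 -0.35 ± 0.05). Mitochondrially encoded transcripts had an adjusted p of 0.0309 by camera, and adjusted p = 0.653 with an estimated correlation.

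Lists that did not pass camera at 48 h were mesenchymal genes (9 up and 3 down of 14, 9 and 4 adjusted over the list alone, adjusted p = 0.0542), replication-dependent histones (1 up and 8 down of 14, adjusted p = 0.102), immediate early genes (12 up and 7 down of 22, adjusted p = 0.264), cysteine and glutathione metabolism (15 up and 14 down of 32, adjusted p = 0.388) and ferroptosis regulators (13 up and 14 down of 29, adjusted p = 0.696). Nor did fatty acid synthesis (6 up and 8 down of 16, adjusted p = 0.535), selenoproteins (7 up and 9 down of 19, adjusted p = 0.585), iron-sulfur cluster assembly (12 up and 9 down of 24, 13 and 9 adjusted over the list alone, adjusted p = 0.258), NF-kappaB genes (7 up and 2 down of 15, adjusted p = 0.212), autophagy and lysosome genes (17 up and 12 down of 34, adjusted p = 0.212), nucleotide synthesis (11 up and 9 down of 23, adjusted p = 0.887), epithelial junction genes (9 up and 9 down of 19, adjusted p = 0.612) and neural and other cell line markers (1 up and 2 down of 5, adjusted p = 0.597) pass. At 48 h the sign of the median depended on the scaling, the filter or a left-out library for the NF-kappaB, epithelial junction and neural lists. Among markers of other cell types at 48 h, CD68 rose by 1.29 ± 0.10 on the log2 scale, and COL1A1 and EGFL7 fell by 1.19 ± 0.09 and 1.39 ± 0.08. With the preset correlation 19 of 32 lists passed at 48 h, and with an estimated correlation 1 did, mitosis and G2/M.

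**Figure D2:**
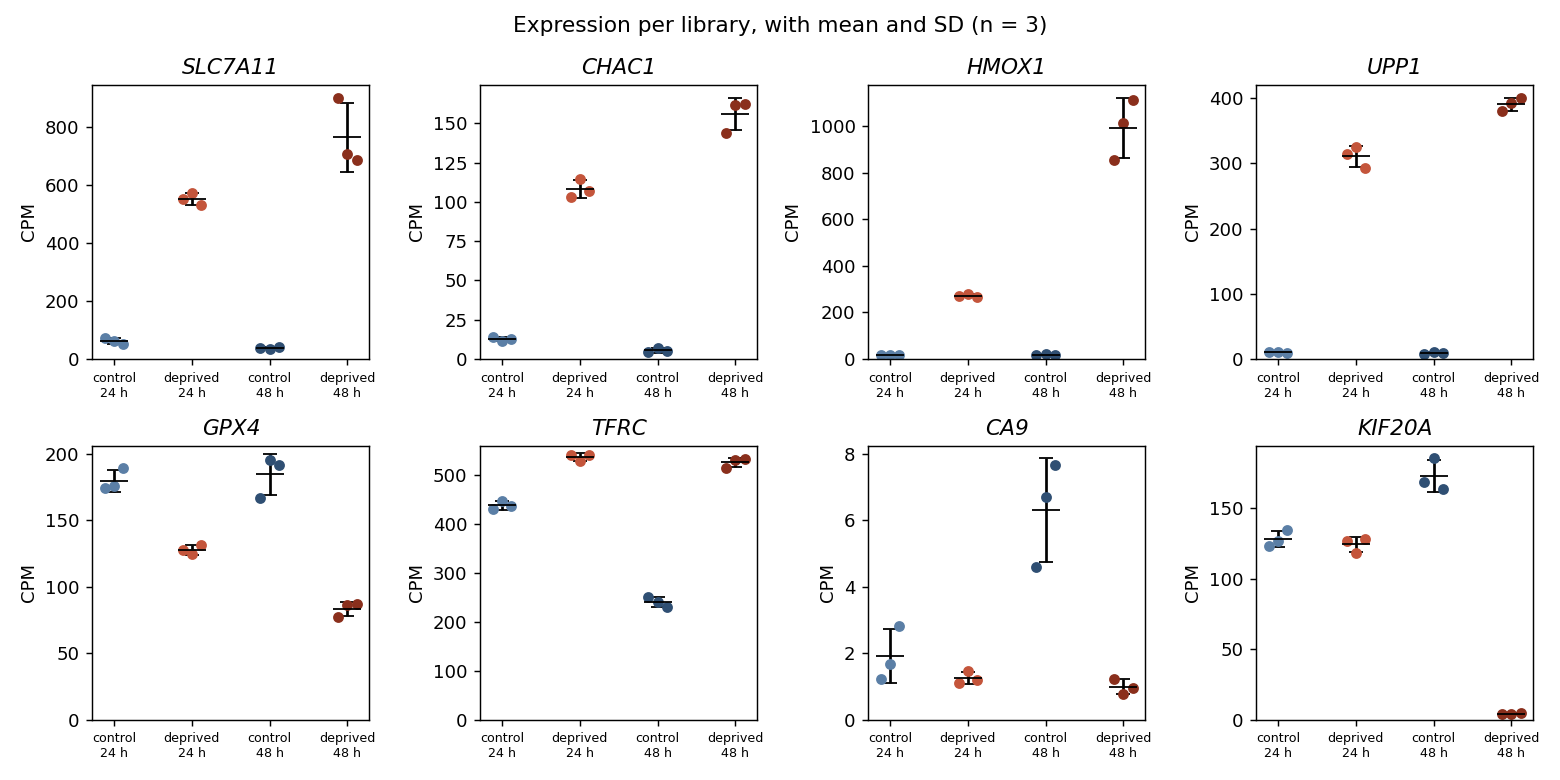
CPM of 8 genes in the 12 libraries (points, y axes starting at 0), with the mean and SD of the 3 libraries of each group in black. HMOX1 reaches 992 ± 129 CPM in deprived cells at 48 h, and KIF20A falls to 4.4 ± 0.395 CPM there.

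The third comparison asked whether the effect of deprivation differed between 24 h and 48 h. The most negative interaction log2 fold changes (± SE) were those of PIF1 -6.06 ± 0.22, KIF20A -5.25 ± 0.10, CENPA -4.73 ± 0.18, HMMR -4.66 ± 0.11 and PIMREG -4.44 ± 0.15, of which KIF20A, CENPA and HMMR belong to the mitosis and G2/M list. The most positive were those of NUPR1 3.16 ± 0.94, UTP14C 2.45 ± 0.42, LCN2 1.89 ± 0.32, FLNC 1.85 ± 0.12 and HSPA1B 1.84 ± 0.15. UTP14C can share reads with a near-identical gene, and the call of NUPR1 was lost without control 24 h replicate 3 (adjusted p = 0.0559). The difference from control cells was larger at 48 h for SLC7A11 1.19 ± 0.15, CHAC1 1.74 ± 0.16, HMOX1 1.71 ± 0.13, TFRC 0.84 ± 0.06 and CTH 0.69 ± 0.11, and smaller for DDIT3 -0.85 ± 0.11. Deprived cells held 536 ± 7.7 CPM of TFRC at 24 h and 525 ± 9.84 at 48 h, while control cells went from 437 ± 8.63 to 240 ± 9.84 CPM. SLC7A11 and CHAC1 also fell in control cells, by 0.72 ± 0.12 and 1.21 ± 0.14 on the log2 scale. For VEGFA, GCLC and MYC the difference was not called (adjusted p = 0.548, 0.071 and 0.128). Without deprived 48 h replicate 1 it was called for GCLC (adjusted p = 0.024), and without deprived 48 h replicate 3 for MYC (adjusted p = 0.028). The interaction was called in 6048 genes by edgeR at an adjusted p under 0.05, 2787 positive and 3261 negative. With library totals alone as the scale the majority turned, to 3347 positive and 2847 negative.

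Genes called at both times went mostly the same way. Of these, 3843 were higher at both times, where 1635 would be from independent lists, and 3626 were lower at both, where 1593 would be. Opposite directions were found for 353 genes higher then lower and 169 lower then higher, against 1705 and 1527 from independent lists. Of the 7469 genes with the same direction, 2709 had a larger effect at 48 h and 280 a smaller 1 by the interaction test. Across genes, which are not independent replicates, the fold changes at both times had a Pearson correlation of 0.711 and a Spearman correlation of 0.722. The times share no control samples.

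Mitosis and G2/M genes had a positive interaction in 0 of 40 members and a negative 1 in 40, with a median of -3.69 (CDC20 -3.97 ± 0.09, CCNB1 -3.87 ± 0.09). The mitosis list had an adjusted p of 1.96e-64 by camera, and adjusted p = 0.00109 with an estimated correlation. Heat shock proteins had a positive interaction in 11 of 12 members and a negative 1 in 0, with a median of 0.86 (HSPA8 1.55 ± 0.09, HSP90AA1 1.14 ± 0.06). Heat shock proteins had an adjusted p of 6.99e-12 by camera, and adjusted p = 0.115 with an estimated correlation. Cytosolic ribosomal protein genes had a positive interaction in 0 of 75 members and a negative 1 in 59 (0 and 64 adjusted over the list alone), with a median of -0.35 (RPS9 -0.76 ± 0.09, RPL31 -0.69 ± 0.08). Cytosolic ribosomal protein genes had an adjusted p of 7.96e-17 by camera, and adjusted p = 0.398 with an estimated correlation. Hypoxia and HIF targets had a positive interaction in 0 of 25 members and a negative 1 in 19 (0 and 22 adjusted over the list alone), with a median of -0.68 (ANKRD37 -2.68 ± 0.27, ALDOC -1.88 ± 0.17). The hypoxia list had an adjusted p of 2.6e-08 by camera, and adjusted p = 0.379 with an estimated correlation. Replication-dependent histones had a positive interaction in 0 of 14 members and a negative 1 in 11, with a median of -1.78 (H1-2 -3.13 ± 0.17, H2BC12 -1.03 ± 0.12). The median was -1.002 over the 4 histone genes with a mean of at least 5 CPM. Replication-dependent histones had an adjusted p of 0.000235 by camera, and adjusted p = 0.0951 with an estimated correlation. Histone copies are near-identical and can share reads. In all, 17 of 32 lists passed for the interaction with the preset correlation, and 1 with an estimated correlation.

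**Figure D3:**
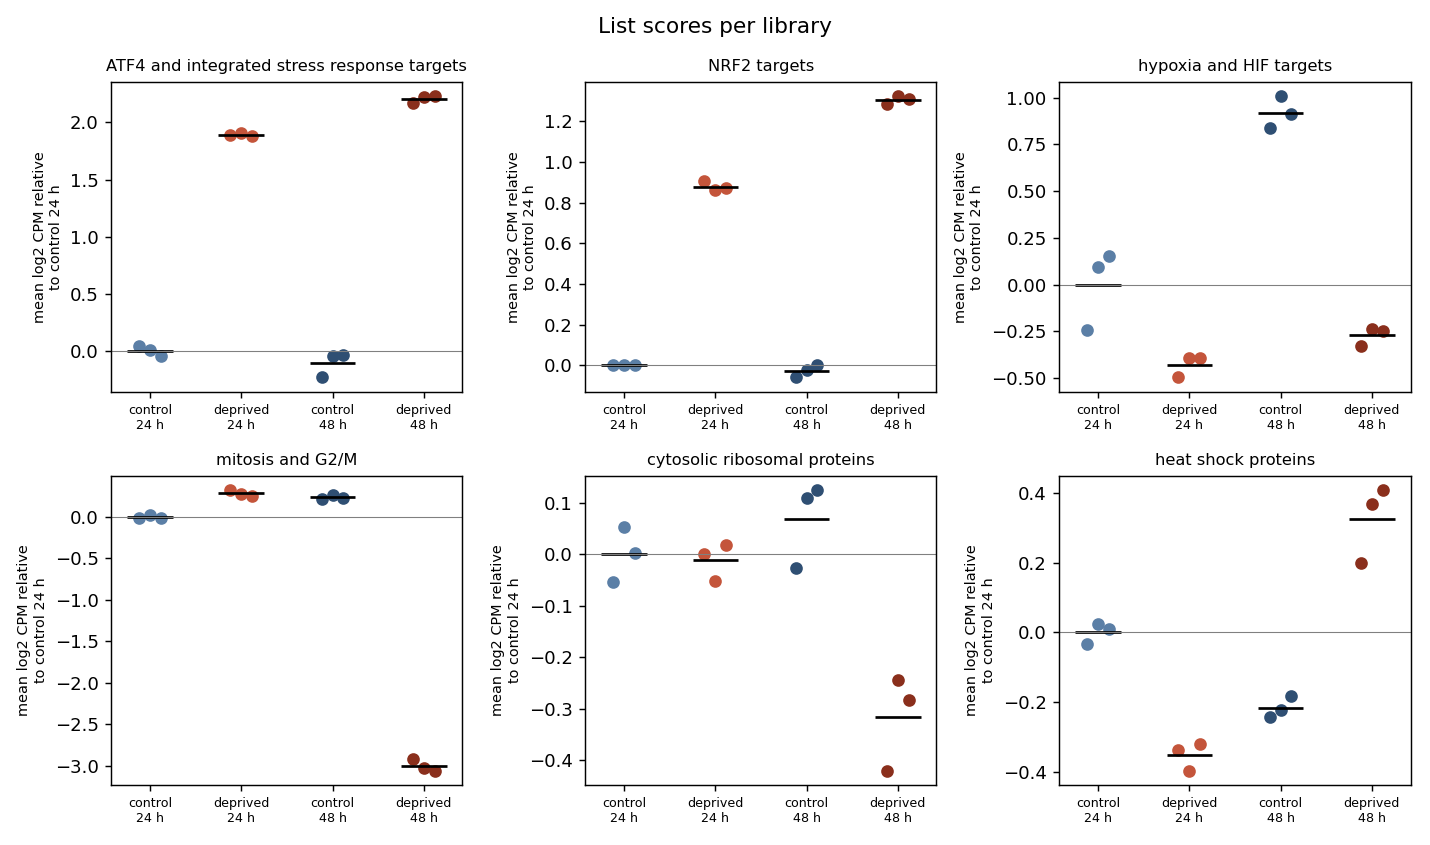
Mean log2 CPM of 6 gene lists in each of the 12 libraries, relative to the mean of control cells at 24 h (points), with the group mean as a black line. The mitosis and G2/M list drops in the 3 deprived libraries at 48 h, where its median log2 fold change against control is -3.27.

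The fourth comparison followed control cells from 24 h to 48 h. Hypoxia and HIF targets rose in 24 of 25 members and fell in 0, with a median log2 fold change of 0.70 (ANKRD37 2.87 ± 0.16, SLC2A3 1.52 ± 0.10, NDRG1 1.33 ± 0.09). The hypoxia list had an adjusted p of 6.5e-27 by camera, and adjusted p = 0.0706 with an estimated correlation. Immediate early genes rose in 20 of 22 members and fell in 0 (21 and 0 adjusted over the list alone), with a median log2 fold change of 0.85 (EGR1 2.32 ± 0.08, KLF4 1.33 ± 0.07). Immediate early genes had an adjusted p of 6.92e-27 by camera, and adjusted p = 0.0683 with an estimated correlation. Glycolysis genes rose in 11 of 15 members and fell in 1 (12 and 1 adjusted over the list alone), with a median log2 fold change of 0.39 (ALDOA 0.84 ± 0.09, PGK1 0.68 ± 0.07). Glycolysis genes had an adjusted p of 4.68e-07 by camera, and adjusted p = 0.246 with an estimated correlation. DNA replication and E2F targets rose in 1 of 40 members and fell in 27 (1 and 31 adjusted over the list alone), with a median log2 fold change of -0.33 (MCM4 -0.97 ± 0.06, MCM5 -0.91 ± 0.07). DNA replication and E2F targets had an adjusted p of 1.08e-14 by camera, and adjusted p = 0.103 with an estimated correlation. The mitosis and G2/M list went the other way in control cells, with a median log2 fold change of 0.229. Targets of p53 rose in 2 of 25 members and fell in 14 (2 and 16 adjusted over the list alone), with a median log2 fold change of -0.31 (TIGAR -0.84 ± 0.07, MDM2 -0.63 ± 0.06). Targets of p53 had an adjusted p of 4.68e-07 by camera, and adjusted p = 0.0683 with an estimated correlation. For time in control cells, 22 of 32 lists passed with the preset correlation and 0 with an estimated correlation.

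Other large rises in control cells were TMEM200B 2.24 ± 0.30, ARRDC4 2.01 ± 0.09 and FOS 1.94 ± 0.12, and other large falls UTP14C -2.73 ± 0.33, LONRF2 -1.32 ± 0.15, RN7SK -1.21 ± 0.21 and CHAC1 -1.21 ± 0.14. In all, 3911 genes changed by edgeR at an adjusted p under 0.05, 2151 higher and 1760 lower. When library totals alone set the scale, 1697 were higher and 2580 lower, so the balance of directions in control cells depends on the scaling.

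The fifth comparison followed deprived cells from 24 h to 48 h. Mitosis and G2/M genes rose in 0 of 40 members and fell in 40, with a median log2 fold change of -3.31 (CCNB1 -3.74 ± 0.07, MKI67 -3.78 ± 0.07). The mitosis list had an adjusted p of 5.4e-56 by camera, and adjusted p = 0.00141 with an estimated correlation. Replication-dependent histones rose in 0 of 14 members and fell in 13 (0 and 14 adjusted over the list alone), with a median log2 fold change of -1.72 (H1-2 -2.73 ± 0.12, H2BC12 -1.03 ± 0.09). Over the 4 histone genes with a mean of at least 5 CPM the median was -0.87. Replication-dependent histones had an adjusted p of 2.01e-05 by camera, and adjusted p = 0.0319 with an estimated correlation. DNA replication and E2F targets rose in 2 of 40 members and fell in 34, with a median log2 fold change of -0.72 (RRM2 -2.08 ± 0.08, TK1 -1.91 ± 0.06). DNA replication and E2F targets had an adjusted p of 8.09e-16 by camera, and adjusted p = 0.2 with an estimated correlation. Heat shock proteins rose in 10 of 12 members and fell in 1, with a median log2 fold change of 0.62 (HSPA8 1.41 ± 0.07, DNAJA1 0.83 ± 0.06). Heat shock proteins had an adjusted p of 1.38e-07 by camera, and adjusted p = 0.2 with an estimated correlation.

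The largest rises in deprived cells were MMP1 3.33 ± 0.30, CXCL8 2.86 ± 0.17, KRT16 2.31 ± 0.23, HSPA1B 2.04 ± 0.11 and DYSF 1.95 ± 0.14, of which MMP1 is a collagenase and CXCL8 a chemokine. The largest falls were PIF1 -5.52 ± 0.19, KIF20A -4.82 ± 0.08, DHRS2 -4.53 ± 0.15, CENPA -4.36 ± 0.14 and SPDYA -4.29 ± 0.17. In all, 7220 genes changed by edgeR at an adjusted p under 0.05, 3512 higher and 3708 lower. The majority turned, to 3715 higher and 3532 lower, under RLE scaling, to 3702 and 3572 under upper-quartile scaling and to 3448 and 3297 with DESeq2.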

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

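The comparison of the hypoxia list with control cells at 24 h was a test chosen only after the lists had been seen. The results of this part stand out because the effect of deprivation differed between 24 h and 48 h by the interaction test, called in 6048 genes, or because they come from data outside the comparisons.

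Of 100 splits of control and deprived labels within each time, 8 gave at least as many interaction calls as the real split, itself included. The real split gave 6048 genes and the highest other split 12135, which points to a structure of the samples. The 7 others all kept or swapped every label of at least 1 time, which carries the effect of deprivation at that time into the contrast. Such splits are no fair null for an interaction, so the count of 8 neither excludes chance nor speaks for it. The 75 splits that mixed labels at both times gave at most 0 genes. Such mixed splits put the effect of deprivation into the spread within groups, which removes calls by construction. For deprivation at 24 h, deprivation at 48 h, time in control cells and time in deprived cells there are 10 splits each, too few for a share under 0.05. The real split gave 9451, 11615, 3911 and 7220 genes, and the highest other split gave 0 in each, so that 1 of 10 reached the real value. The other splits here are all mixed, with the real effect inside their groups. Their 0 calls therefore do not measure what chance would give.

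The mitosis and G2/M list had a median log2 fold change of 0.32 at 24 h, where 26 of 40 members rose and 3 fell, and of -3.27 at 48 h, where all 40 fell, an interaction of -3.69. With an estimated correlation the list's call was lost at 24 h (adjusted p = 0.168) and kept at 48 h (adjusted p = 0.0265). The choice of scaling mattered little: under RLE, upper-quartile and total-count scaling the median was at least 0.241 at 24 h and at most -3.262 at 48 h. These scalings moved the median of all genes no further than -0.08 at 24 h and -0.074 at 48 h. They could thus hardly have turned the list, and they cannot show a change in total RNA per cell. The values argue against any deviating library. With each of the 6 libraries left out in turn the median was at least 0.312 at 24 h and at most -3.189 at 48 h. A candidate explanation is that deprived cells had largely stopped dividing by 48 h, which stays a hypothesis since cell numbers were not used here.

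Hypoxia and HIF targets had an interaction of -0.68, and 24 of 25 members rose between 24 h and 48 h in the control cells (adjusted p = 0.379 and 0.0706 with an estimated correlation). If that rise were the whole cause of the lower level at 48 h, deprived cells at 48 h should match control cells at 24 h. Against those, their median was -0.408, with 16 of 25 members lower and 7 higher, but fry's p of 0.0883 missed the threshold. A rise after 24 h cannot account for the level at 24 h, where 15 of 25 members were lower and 1 higher (median -0.474, adjusted p = 0.00667 by fry, and adjusted p = 0.464 by camera with an estimated correlation). A rise in control cells before 24 h was not tested, since no sample was taken earlier. The list's scores also spread most in control cells at 24 h, with an SD of 0.213. From 24 h to 48 h the list's median rose by 0.187 in deprived cells (0.11 to 0.263 with 1 library left out). In control cells it rose by 0.697. The values thus argue against a fall in deprived cells as the source of the wider difference at 48 h, which went with the rise in control cells. The part already present at 24 h stays unexplained. The effect of a wash and fresh medium, which the labels describe for deprived cells only, also stays open.

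Cytosolic ribosomal protein genes had an interaction of -0.35 and a median of -0.363 at 48 h (adjusted p = 0.398 and 0.528 with an estimated correlation). With each library left out in turn the median was at most -0.302, which argues against any deviating library. Genes of like abundance had a median of 0.034, and 1000 draws of them ranged from -0.257 to 0.272, which argues against a shift of all abundant transcripts. Genes of like length had a median of -0.098, and their draws from -0.47 to 0.353 include the list's value, so a loss of short transcripts cannot be told apart and may contribute.

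Among the other lists that passed camera for the interaction with the preset correlation, those with a positive median were heat shock proteins (0.86), ATF4 targets (0.46), amino acid transporters (0.37), NRF2 targets (0.28), aminoacyl-tRNA synthetases (0.25), ribosome biogenesis (0.19), autophagy and lysosome genes (0.12), nuclear-encoded oxidative phosphorylation (0.10) and ferroptosis regulators (0.10). Those with a negative median were replication-dependent histones (-1.78), interferon-stimulated genes (-0.67), DNA replication and E2F targets (-0.49), immediate early genes (-0.45) and glycolysis (-0.35). With an estimated correlation, the smallest adjusted p among these was that of the histones, at 0.0951. A negative interaction need not mean a fall in deprived cells. From 24 h to 48 h, medians in deprived and control cells were -0.1 and 0.394 for glycolysis and 0.445 and 0.845 for immediate early genes. For interferon-stimulated genes they were -0.096 and 0.338. They were -1.716 and 0.224 for the histones and -0.719 and -0.334 for DNA replication and E2F targets.

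Rows of the table without a gene name were not used in the comparisons. Of 206 with enough counts, 21 were higher and 41 lower in deprived cells at 24 h, and 33 were higher and 70 lower at 48 h.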

How the results depend on the processing

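Scaling by library totals was chosen after seeing the data. Counts of changed genes stayed within 1.5 times of the reported ones under RLE and upper-quartile scaling, total-count scaling, DESeq2, both filters, the smaller fits (not made for the interaction, which uses all 12 samples) and leaving out any of the 12 samples; the lowest of the last were 8587 at 24 h, 11113 at 48 h, 5352 for the interaction, 2914 for time in control cells (without control 24 h replicate 1) and 6240 for time in deprived cells. Genes called the same way at both times numbered 6993 with DESeq2 and 7293 without a filter, against 7469 reported, and the Pearson correlation of fold changes was 0.756 over genes with a mean of at least 5 CPM.

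For the 757 values that the rule for named genes takes, 13386 were recomputed. Upper-quartile and total-count scaling were left out of this tally. They moved the median log2 fold change of all genes at 24 h to -0.077 and -0.08, against -0.006 as reported. Of these, 13255 kept their direction and their side of the threshold, 81 lost the call, 13 gained it and 37, of 17 values, changed direction. None of those 17 was called as reported.

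The number of lists past the threshold depended on the correlation between members: with an estimated correlation it was 0 at 24 h, 1 at 48 h and 1 for the interaction, against 20, 19 and 17 with the preset value. Fry, which does not compare a list with other genes, called 30 at 48 h. The larger estimated correlations widen the null by construction.

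Replicate numbers may pair the samples in part: 8 of 18 same-number pairs correlated above 0.1 (range -0.108 to 0.303) and 6 of 12 samples were closest to their own number. Some pairs with different numbers also passed 0.1, up to 0.215 for control 24 h replicate 3 with control 48 h replicate 2. A correlation above 0.1 alone therefore does not mark a pair. With the replicate block, 9631, 11734, 6329, 4306 and 7473 genes changed in the order of the comparisons, each above the reported count. With it, 20, 20 and 17 lists passed at 24 h, at 48 h and for the interaction. The interaction of GCLC was called with the block (adjusted p = 0.0355) and over genes with a mean of at least 5 CPM (adjusted p = 0.0466), and not as reported.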

Other observations

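The pathways and genes of this part were chosen after their values were seen, except for the test of cysteine content. At 48 h without cystine, the class I heavy chains HLA-B and HLA-C fell by 1.13 ± 0.06 and 1.16 ± 0.06 on the log2 scale (SE). HLA-E fell by 1.74 ± 0.06, and B2M, the class I light chain, fell by 1.35 ± 0.06, from 451 ± 18 to 177 ± 10.9 CPM (SD, n = 3). TAP2, a peptide transporter subunit, rose by 0.54 ± 0.07 while TAP1 fell by 0.76 ± 0.06. NLRC5 and CIITA, regulators of class I and class II genes, were not called at 48 h (adjusted p = 0.126 and 0.476), and NLRC5 fell by 0.45 ± 0.12 at 24 h. B2M rose in control cells, from 341 ± 20.8 CPM at 24 h, which widened its difference at 48 h. Its level in deprived cells at 48 h also lay below that of control cells at 24 h. Class II genes were low. HLA-DRA went from 7.07 ± 0.443 CPM in control cells at 48 h to 0.467 ± 0.176 in deprived cells. HLA genes resemble each other closely and can share reads. The deposited table names KEGG pathways, and the 312 within a set range of size were tested. That of antigen processing and presentation passed camera at 24 h (9 up and 32 down of 85, adjusted p = 0.0252, and adjusted p = 0.322 with an estimated correlation). It did not pass at 48 h (16 up and 41 down of 85, adjusted p = 0.0944, and adjusted p = 0.393 with an estimated correlation). That of graft-versus-host disease fell in 18 of 24 members at 48 h and rose in 1, with a median of -1.77. Camera gave the last an adjusted p of 0.00175, and adjusted p = 0.222 with an estimated correlation. At 24 h it fell in 14 members and rose in 0 (adjusted p = 0.0382, and adjusted p = 0.322 with an estimated correlation).

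Of 38 genes with PSMA, PSMB, PSMC or PSMD symbols, which encode proteasome subunits and some assembly factors, 11 rose and 19 fell at 24 h (median -0.16). At 48 h, 31 rose and 6 fell (median 0.39). The KEGG proteasome pathway had a positive interaction in 36 of 50 members and a negative 1 in 4 (median 0.43). Its adjusted p was 9.44e-11, and adjusted p = 0.61 with an estimated correlation. Control cells changed too, so the difference at 48 h is not all a rise in deprived cells. PSMD2 went from 451 ± 11.6 to 284 ± 14 CPM in control cells, against 418 ± 34.9 in deprived cells at 48 h. PSMC4 went from 75.6 ± 0.439 to 56.4 ± 3.32 CPM in control cells, against 127 ± 7.96 in deprived cells at 48 h. Genes of SNARE interactions in vesicle transport rose in 24 of 36 at 48 h and fell in 5, with a median of 0.59. Their adjusted p was 0.00586, and adjusted p = 0.267 with an estimated correlation. At 24 h they did not pass (14 up and 5 down, adjusted p = 0.0728).

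A hypothesis written before its test was that transcripts encoding cysteine-rich proteins are lowered when cystine is withheld. Across 13432 genes, which are not independent replicates, the share of cysteine in the encoded protein had a Spearman correlation of -0.087 with the log2 fold change at 24 h and -0.064 at 48 h. Cysteine ranked 2 from the lowest of the 20 amino acids at 24 h, after tryptophan, and 1 at 48 h. Both values fell between the bounds set in advance for and against the hypothesis, so the test leaves it undecided, and any relation may be weak.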
